A study of Mus musculus with 224 samples.

How the data were processed

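Transcript levels were measured by RNA sequencing in liver, soleus muscle and visceral adipose tissue of mice of 3 inbred strains (BALB/cJ, DBA/2J and C57BL/6J). The animals were fed a high-fat diet (HFD) or regular chow (RC) and sampled on day 5, 13 or 33 by the sample labels. In each tissue the 3 strains, 2 diets and 3 days gave 18 groups of 4 animals, 72 animals in all, and the labels give all 3 tissues for each animal. Of the 224 samples of the series, 216 were used. The 8 liver libraries whose titles end in a letter, from 4 animals, were not analysed here because the tables used held no column for them.

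Per the labels' protocols, RNA was extracted with an RNeasy Plus micro kit, libraries were made with a stranded TruSeq mRNA kit, and single reads were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, STAR 2.5.3a and edgeR were used with genome build GRCm38. The role of each tool, the read counter, the annotation, the filter on low counts and the name of the scaling method were not given in the sources used here. The deposited values are log2 CPM (read counts scaled by library size), relative to library sizes that include a scaling factor per library. The prior count was 0.25 reads at the mean library size in liver and 2 reads in muscle and adipose tissue, worked out from the values. Whole reads were recovered from them: 100% of values under 2000 reads came out whole within 0.05 reads in each tissue. The header line of each table is 1 cell short, so each title was taken to name the column after it. Values of 0 reads stood at a log2 CPM of -6.63 in liver, -3.74 in muscle and -3.81 in adipose tissue.

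A gene was tested when its log2 CPM reached 0 in at least 4 animals, which left out 0 genes in liver and muscle and 1 gene in adipose tissue. This gave 12611 tested genes in liver, 13637 in muscle and 16541 in adipose tissue. Gene IDs were matched to GENCODE symbols and coordinates of GRCm38 for 12602, 13624 and 16520 genes of the tables. Reads of all strains were mapped to a C57BL/6J genome, so sequence differences between strains enter the strain differences. Members of gene families with near-identical copies, such as Mup, Cyp3a, Cyp4a, Gstm, Serpina3, the haemoglobin genes and ribosomal protein genes with pseudogenes, are reported with that uncertainty.

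The test was limma (3.58.1, R 4.3.3), a moderated test with a trend of variance on mean level. Each tissue had 1 fit with a mean for each of the 18 groups and 54 residual degrees of freedom. The prior degrees of freedom were 4.11 in liver, 3.57 in muscle and 2.47 in adipose tissue. Values of p were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes of a tissue and contrast, with a threshold of 0.05. The contrasts were HFD minus RC over all strains and days with equal weights, within each strain, and in each of the 9 combinations of strain and day. Further contrasts were the difference of the diet effect between strains or days (F test on 2 contrasts), and pairs of strains on RC. Errors beside log2 fold changes are standard errors from the fit, and errors beside group means are standard deviations over animals.

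Named genes followed a rule. Eligible genes had a mean level at or above the median of the tested genes and a symbol that is no predicted, clone or pseudogene name. For the overall diet effect the 8 highest and 8 lowest log2 fold changes were taken among genes past the threshold with 1 sign in all 9 combinations. Within a strain the 3 highest and 3 lowest with 1 sign on all 3 days were taken. For the differences between strains the 6 genes of smallest p were taken, for those between days the 4 of smallest p, and on RC the 2 highest and 2 lowest per pair with a set of strain check genes. Up to 4 members of smallest p were taken from each described gene list. The design, the gene lists, this rule and the alternatives below, except where stated, were fixed before the data were examined.

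Gene lists (pathways and cell type markers) were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01, and adjusted over the lists of a tissue and contrast. Every list was tested again with an estimated correlation. The fry test asks whether a list's genes move, on balance, in 1 direction, without comparison to other genes. Gene counts of a list were also adjusted over the list alone. Lists with fewer than 3 measured members were not tested. Each count of called genes was compared with counts from other splits of the same animals: diet labels were exchanged within strain and day, with 100 splits drawn or all 35 splits of 8 animals. For strain differences on RC, strain labels were exchanged within days, and the differences between strains or days used the exchanged diet labels.

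Alternatives were no filter, a stricter filter (mean level at or above the median of tested genes), quantile normalization, no variance trend, the number range of the animals as a covariate, only the animals of the comparison in the fit, and leaving out each animal in turn. The animal numbers in the titles fall into a lower, a middle and an upper range whose meaning is not given. Where at least 3 numbers occurred in both diets of a strain and day, the number was also used as a replicate block. Animals of 1 number were taken as pairs where the deviations from their group means correlated over 0.1 in all pairs. This held on day 13 in BALB/cJ for liver (3 pairs, correlations 0.36 to 0.58) and muscle (3 pairs, 0.34 to 0.56) and in no other combination. Alternatives added after seeing the data were voom on the recovered reads, the overall effect within each number range, the mean level of 11 B cell markers of each adipose library as a covariate (with and without the doubted libraries), and fits without 2 adipose libraries (3HF201 and 3HF208) and 1 muscle library (1RC210) whose marker genes stood apart.

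The tests were checked on simulated data with the observed spread, in which 200 genes were changed. Over all strains and days, a log2 change of 1 was recovered for 97% of changed genes in liver, 97% in muscle and 80.6% in adipose tissue. In 4 animals against 4 it was recovered for 67.2%, 83.6% and 32.8%, and a log2 change of 0.5 for 25.4%, 40.3% and 1.5%. Reads, tables and figures were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.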

Results

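RNA sequencing libraries of liver, soleus muscle and visceral adipose tissue were compared in 72 mice of 3 inbred strains. In each tissue 36 animals had been fed a high-fat diet (HFD) and 36 regular chow (RC), with 4 animals for each of the 18 groups of strain, diet and day. Libraries held 1.81e+07 to 3.20e+07 reads in liver, 1.99e+07 to 3.34e+07 in muscle and 1.98e+07 to 4.68e+07 in adipose tissue. The mean depth of the diets differed by less than 1 SD in each tissue. Levels are log2 CPM, fold changes are HFD against RC unless stated, and adjusted p values come from limma.

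Which liver genes differ with diet across strains was asked first. Genes of drug and steroid metabolism were lower on HFD. Cyp3a11 (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964, GRCm38), a cytochrome P450 that oxidises drugs and steroids, stood at 9.99 ± 0.77 (SD, n = 36) on HFD and 12.24 ± 0.46 (SD, n = 36) on RC. This was a 4.75-fold lower level (log2 fold change -2.25 ± 0.11 (SE), adjusted p = 1.03e-24). Its paralog Cyp3a59 fell 2.85-fold, the organic anion transporter Slco1a4 3.2-fold, the coumarin hydroxylase Cyp2a5 2.54-fold, the glutathione transferase Gstm2 2.44-fold and the carboxylesterase Ces2a 2.21-fold (log2 fold change -1.15 ± 0.05, adjusted p = 2.77e-26). Upp2, a uridine phosphorylase, fell 2.52-fold, and Scd1, the stearoyl-CoA desaturase, fell 2.38-fold (log2 fold change -1.25 ± 0.23, adjusted p = 4.34e-05). Vnn1 (ENSMUSG00000037440, chromosome 10, 23894688 to 23905343), a pantetheinase, rose 3.35-fold from 4.14 ± 0.94 to 5.88 ± 1.62 (SD, n = 36 each; log2 fold change 1.75 ± 0.18 (SE), adjusted p = 2.02e-11). The fatty aldehyde dehydrogenase Aldh3a2 rose 1.77-fold, Paqr9 and the fatty acid binding protein Fabp2 1.6-fold, and Eci1 and Ech1, isomerases of fatty acid oxidation, 1.46-fold and 1.43-fold. Nrp1 (log2 fold change 0.57 ± 0.10) and Nxpe2 (0.48 ± 0.07) were higher as well. These 16 genes, chosen among those with 1 direction in all 9 combinations of strain and day, had adjusted p values no higher than 4.34e-05. Reads may be shared among Cyp3a and among Gstm copies, so single members are uncertain.

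In liver 2676 of 12611 genes passed the threshold (21.2%), 1377 higher and 1299 lower on HFD. Within the lower range of animal numbers 3065 genes passed (29 animals), within the middle range 119 (18 animals) and within the upper range 221 (20 animals). The overall direction was kept by 98.4%, 82.4% and 83.3% of the 2676 genes in these ranges.

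Among gene lists, those of fatty acid oxidation were higher and those of sterol synthesis lower in liver. Of 24 measured genes of cholesterol synthesis and uptake, 22 fell (23 adjusted over the list alone), with a median log2 fold change of -0.55, among them Fdps (-1.03 ± 0.14) and Tm7sf2 (-0.73 ± 0.09). Camera gave an adjusted p = 3.32e-19, and adjusted p = 0.0987 with an estimated correlation. Of 16 genes of mitochondrial fatty acid oxidation 15 rose (15 adjusted over the list alone; median 0.27, camera adjusted p = 7.39e-20, adjusted p = 0.0262 with an estimated correlation). Targets of PPAR, a nuclear receptor for fatty acids, rose in 14 of 19 (15 adjusted over the list alone; median 0.45, camera adjusted p = 6.48e-12, adjusted p = 0.0933 with an estimated correlation). Of 18 xenobiotic-metabolising genes 13 fell and 2 rose, with the same counts adjusted over the list alone (median -0.62, camera adjusted p = 3.16e-10, adjusted p = 0.0304 with an estimated correlation). Fatty acid and triglyceride synthesis held 10 genes of 22 that fell (12 adjusted over the list alone; median -0.25, camera adjusted p = 3.57e-05, adjusted p = 0.373 with an estimated correlation). As measured beside these groups, erythroid genes fell in 3 of 5 (4 adjusted over the list alone; median -0.45, camera adjusted p = 0.00463, adjusted p = 0.203 with an estimated correlation). Early stress genes fell in 5 and rose in 1 of 12 (7 and 2 adjusted over the list alone; median -0.33, camera adjusted p = 0.0136, adjusted p = 0.38 with an estimated correlation). Across the overall effect, the calls that held with an estimated correlation were fatty acid oxidation and xenobiotic metabolism in liver and fatty acid oxidation in muscle.

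**Figure D1:**
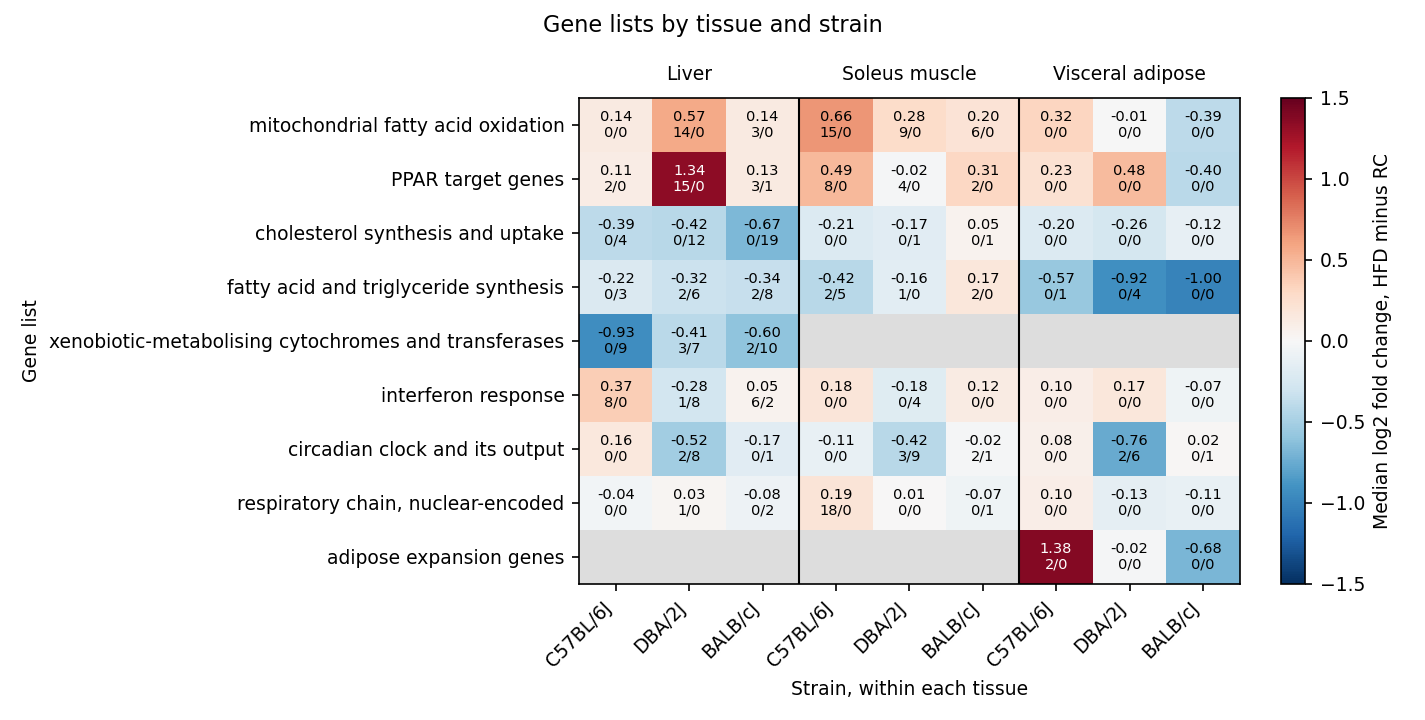
Median log2 fold change (HFD against RC) of 9 gene lists in each strain and tissue, with the numbers of members that passed the threshold as higher and lower. In DBA/2J liver the median of the 19 PPAR targets was 1.34 with 15 members higher, and in liver of C57BL/6J 8 of 21 interferon genes were higher.

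Strains were then asked whether they respond alike. In DBA/2J liver the microsomal fatty acid hydroxylases of the PPAR response rose most. Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142) stood at 9.88 ± 3.09 on HFD and 3.64 ± 1.25 on RC (SD, n = 12 each), a 75.8-fold rise (log2 fold change 6.24 ± 0.73 (SE), adjusted p = 1.94e-09). This mean over days joins log2 fold changes of 7.80 on day 5, 2.95 on day 13 and 7.98 on day 33. Cyp4a10 rose 28-fold and the acyl-CoA thioesterase Acot1 6.18-fold, while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 6.52-fold (log2 fold change -2.70 ± 0.44, adjusted p = 4.2e-06). Upp2 fell 4.56-fold and Cyp3a11 5.09-fold. Of 19 PPAR targets 15 rose in DBA/2J (17 adjusted over the list alone; median 1.34, camera adjusted p = 4.07e-20, adjusted p = 0.0132 with an estimated correlation), among them Ehhadh (2.06 ± 0.21) and Acaa1b (1.80 ± 0.18). Of 16 fatty acid oxidation genes 14 rose, with the same count adjusted over the list alone (median 0.57, camera adjusted p = 1.67e-24, adjusted p = 0.00781 with an estimated correlation). Clock genes held 8 that fell and 2 that rose among 18 (9 and 4 adjusted over the list alone; median -0.52), and camera did not call them (adjusted p = 0.0564, and adjusted p = 0.585 with an estimated correlation). Among these clock genes Arntl rose by 2.15 ± 0.51 and Per2 had a log2 fold change of -1.08 ± 0.24.

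In C57BL/6J liver the major urinary proteins Mup9, Mup18 and Mup17 rose 4.15-fold, 4.11-fold and 3.43-fold (n = 12 each), genes whose near-identical copies cannot be separated with certainty. Cyp3a59 fell 4.49-fold, Gstm3 4.45-fold (log2 fold change -2.15 ± 0.31, adjusted p = 3.07e-06) and Cyp3a11 4.42-fold (-2.14 ± 0.19, adjusted p = 6.06e-13). Interferon-stimulated genes rose in 8 of 21 (19 adjusted over the list alone; median 0.37, camera adjusted p = 1.2e-18, adjusted p = 0.00306 with an estimated correlation), such as Ifi44 (0.75 ± 0.16), Rtp4 (0.47 ± 0.10) and Irgm1 (0.37 ± 0.08). Xenobiotic genes fell in 9 of 18 (11 adjusted over the list alone; median -0.93, camera adjusted p = 1.2e-18, adjusted p = 0.00122 with an estimated correlation), among them Gsta2 (-1.91 ± 0.26) and Gstm1 (-1.20 ± 0.15). Cholesterol genes fell in 4 of 24 (17 adjusted over the list alone; median -0.39, camera adjusted p = 8.17e-13, adjusted p = 0.352 with an estimated correlation).

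In BALB/cJ liver sterol genes fell, with Sqle, the squalene epoxidase, 4.74-fold lower (log2 fold change -2.25 ± 0.32 (SE), n = 12 each, adjusted p = 1.69e-06). The lipin Lpin1 fell 4.55-fold and Cyp3a11 4.78-fold, while Cyp4a14 rose 6.24-fold from 4.98 ± 2.91 to 7.62 ± 2.81 (SD, n = 12 each; adjusted p = 0.00884; log2 fold changes 4.43, 3.17 and 0.33 on days 5, 13 and 33), Vnn1 rose 3.05-fold and the magnesium transporter Slc41a2 2.22-fold. Of the 24 cholesterol genes 19 fell (22 adjusted over the list alone; median -0.67, camera adjusted p = 9.07e-18, adjusted p = 0.239 with an estimated correlation), including Msmo1 (-1.33 ± 0.24), Tm7sf2 (-1.16 ± 0.16) and Cyp51 (-1.16 ± 0.20). Xenobiotic genes fell in 10 and rose in 2 of 18 (12 and 2 adjusted over the list alone; median -0.60, camera adjusted p = 2.01e-06, adjusted p = 0.239 with an estimated correlation).

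The threshold was passed by 291 genes in C57BL/6J liver (129 higher, 162 lower), 2718 in DBA/2J (1332 higher, 1386 lower) and 1866 in BALB/cJ (995 higher, 871 lower). With only genes of at least median level tested, BALB/cJ had 381 higher and 635 lower genes, and with only the strain's own animals in the fit C57BL/6J had 183 and BALB/cJ 961. The diet effect itself differed between strains for 1974 genes, among them Acot1 (adjusted p = 1.14e-05), Mup17 (4.19e-05), Cyp4a10 (0.00013), Cyp4a14 (0.000133) and Cyp7a1 (0.00929), while Cyp3a11 did not pass that test (0.855). By smallest p the genes were Slc46a3, Hsdl2, C2, Gpr155, Irf7 and Prnp. Slc46a3, a lysosomal transporter, had log2 fold changes of 0.25 in C57BL/6J, -1.40 in DBA/2J and -0.26 in BALB/cJ (SE 0.11 each, adjusted p = 1.16e-10). Hsdl2 had 1.24 in DBA/2J against 0.14 and 0.08 in C57BL/6J and BALB/cJ (SE 0.10), and Irf7, an interferon regulatory factor, had 0.37, -0.80 and -0.26 in C57BL/6J, DBA/2J and BALB/cJ (SE 0.10). The complement gene C2 had 0.06, -0.91 and -0.42 (SE 0.08), Gpr155 0.20, -0.88 and -0.08 (SE 0.09), and the prion protein gene Prnp 0.21, -0.77 and -0.36 (SE 0.08) in the same order. For all 6 genes DBA/2J differed from C57BL/6J (adjusted p from 3.65e-11 to 4.64e-07) and from BALB/cJ (6.39e-07 to 0.0217), while Hsdl2 (0.886) and Gpr155 (0.241) did not differ between BALB/cJ and C57BL/6J. Interferon genes responded lower in DBA/2J than in C57BL/6J in 12 of 21 (16 adjusted over the list alone; median -0.67, camera adjusted p = 2.16e-14, adjusted p = 0.0278 with an estimated correlation). PPAR targets responded higher in DBA/2J than in C57BL/6J in 13 of 19 (15 adjusted over the list alone; median 1.5, camera adjusted p = 2.16e-14, adjusted p = 0.049 with an estimated correlation).

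The diet effect differed between days for 422 liver genes. Tnfaip8l1 had log2 fold changes of -0.30 on day 5, 0.58 on day 13 and 0.43 on day 33 (adjusted p = 8e-05). Ginm1 had -0.30, 0.30 and -0.29, and the carboxylesterase Ces3a -0.41, 0.27 and 0.09 (n = 12 for each diet and day). By day, 17, 40 and 115 genes passed in C57BL/6J on days 5, 13 and 33, 879, 241 and 2005 in DBA/2J, and 1574, 46 and 1210 in BALB/cJ (4 animals against 4). With animals of 1 number as a block, the 46 genes of BALB/cJ on day 13 became 1, Gsta2 (log2 fold change -2.31 ± 0.12, adjusted p = 0.034; named after its value was seen). With only the 8 animals compared in the fit, C57BL/6J had 1 gene on day 5 and 10 on day 33, DBA/2J 951 on day 13, and BALB/cJ 38, 14 and 574 on days 5, 13 and 33. Single animals moved several counts: on day 5 C57BL/6J had 11 genes without 1RC251, 28 without 1HF227 and 30 without 1HF249, and DBA/2J 547 without 2HF202 or 2RC203. On day 33 BALB/cJ had 551 without 3RC209, 702 without 3HF258, 712 without 3HF208 and 718 without 3RC208. Leaving out each of 5 animals moved the count of BALB/cJ on day 5, from 761 without 3RC203 to 2501 without 3HF224. The same held for 7 animals of C57BL/6J on day 33 (24 without 1HF259 to 2.2e+02 without 1HF257), 8 of DBA/2J on day 13 (66 without 2HF253 to 159 without 2HF231), 5 of C57BL/6J on day 13 (22 without 1HF252 to 62 without 1HF230) and 5 of BALB/cJ on day 13 (20 without 3RC255 to 30 without 3RC228).

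**Figure D2:**
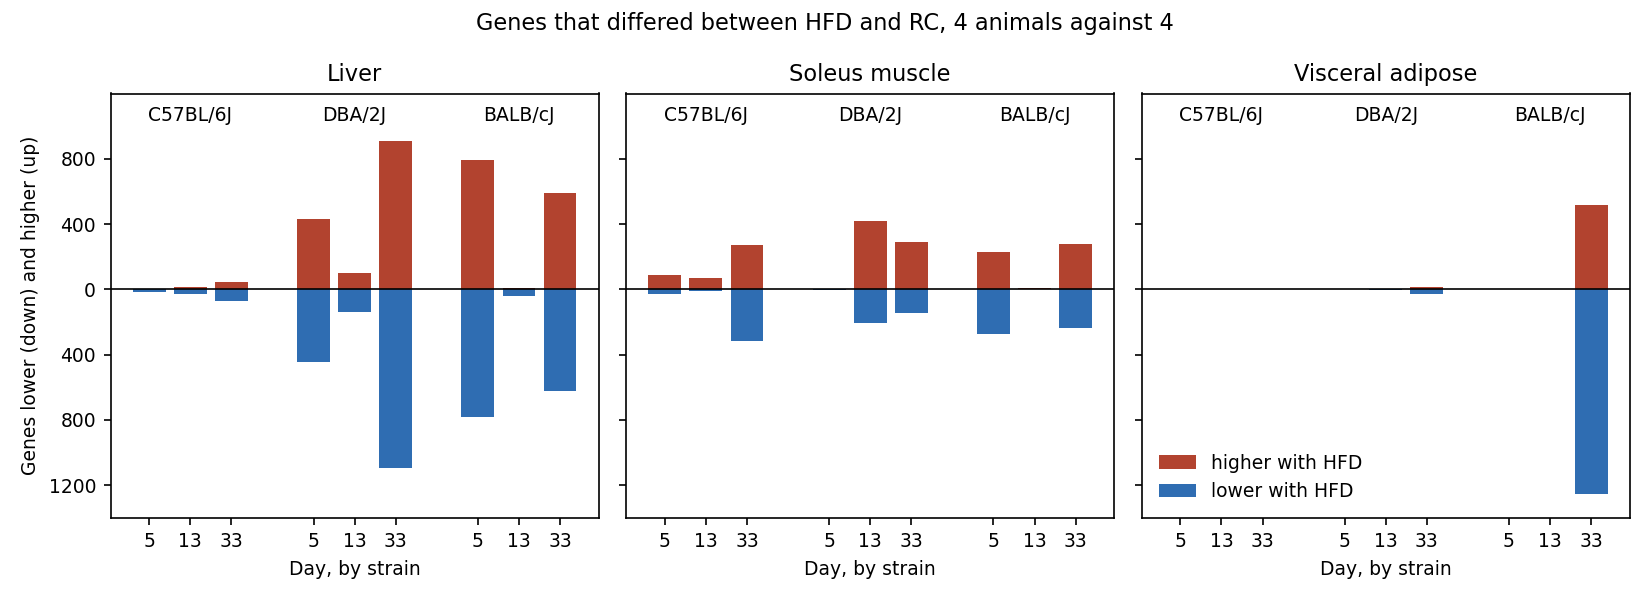
Numbers of genes higher and lower with HFD at an adjusted p under 0.05 in each strain, day and tissue (bars, 4 animals against 4). DBA/2J liver on day 33 had 2005 genes, and adipose tissue of BALB/cJ on day 33 had 1769 genes, which became 299 without the adipose libraries 3HF201 and 3HF208.

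How the strains differ on RC sets the background of these effects. In liver 6071 genes differed between DBA/2J and C57BL/6J, 5899 between BALB/cJ and C57BL/6J and 5310 between BALB/cJ and DBA/2J (12 animals each). Hc, the complement gene whose product DBA/2J mice lack, was lower in DBA/2J than in C57BL/6J (log2 fold change -2.20 ± 0.11, adjusted p = 9.29e-26) and did not pass in BALB/cJ against C57BL/6J (-0.20, adjusted p = 0.13). Glo1 was higher in DBA/2J (0.84 ± 0.07, adjusted p = 5.46e-17) and in BALB/cJ (0.85, adjusted p = 2.7e-17) than in C57BL/6J, as was Alad (1.48 and 1.43). Nnt, in which C57BL/6J mice carry a deletion, went against the strain labels: it was lower in DBA/2J than in C57BL/6J (-0.97 ± 0.17, adjusted p = 4.99e-06) and did not pass in BALB/cJ (-0.18, adjusted p = 0.406). Its mean level was low (-0.47). Largest among eligible genes were Serpina3c (8.61 ± 0.34 and 8.67 in DBA/2J and BALB/cJ against C57BL/6J), Mup11 (-8.10 ± 0.31 and -8.07) and Mug2 (-4.70 ± 0.20 and -5.23). The hepcidin Hamp2 was higher in DBA/2J than in C57BL/6J (5.86 ± 0.37), Obp2a in BALB/cJ than in C57BL/6J (6.82 ± 0.46), and Mup12 (8.21 ± 0.25) and Mme (3.82 ± 0.25) in BALB/cJ than in DBA/2J. Hamp2 (-6.60 ± 0.37) and Rpl26 (-4.73 ± 0.11) were lower in BALB/cJ than in DBA/2J. Since reads were mapped to a C57BL/6J genome, these include sequence differences and multicopy families (Serpina3, Mup, Rpl26 copies).

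In soleus muscle genes of fatty acid use were higher on HFD across strains. Fabp3 (ENSMUSG00000028773, chromosome 4, 130308595 to 130315463), the muscle fatty acid binding protein, stood at 10.17 ± 0.28 on HFD and 9.23 ± 0.69 on RC (SD, n = 36 each), 1.92-fold higher (log2 fold change 0.94 ± 0.10 (SE), adjusted p = 2.12e-10). The thioesterase Acot2 rose 1.88-fold, the mitochondrial carrier Slc25a34 1.83-fold, Rab15 1.76-fold, the muscle fructose bisphosphatase Fbp2 1.72-fold, the lipid droplet protein Plin5 1.7-fold, Btnl9 1.69-fold and Ech1 1.57-fold (0.65 ± 0.05, adjusted p = 1.61e-14). Itm2a fell 1.53-fold (-0.61 ± 0.08, adjusted p = 2.08e-07), the glutamine synthetase Glul 1.41-fold and the glycerol phosphate dehydrogenase Gpd1 1.34-fold (adjusted p = 0.00565). Log2 fold changes of the other named genes that fell were -0.53 ± 0.10 for Slc8a3, -0.51 ± 0.09 for Ociad2, -0.41 ± 0.08 for Osbpl6, -0.39 ± 0.09 for Cmbl and -0.36 ± 0.09 for Slc37a4, the glucose 6-phosphate transporter. The 16 genes, chosen in the same way as in liver, had an adjusted p no higher than 0.00565. The chow library 1RC210 of C57BL/6J on day 33 had slow fibre genes at a median of -6.29 and fast fibre genes at 1.96 (log2) from the other animals of its group; without it all 16 genes still passed.

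Of 13637 muscle genes 2368 passed, 1224 higher and 1144 lower, and without 1RC210 also 2368 (1183 higher, 1185 lower), of which 2160 were shared. Within the lower, middle and upper number ranges 1346, 1063 and 163 genes passed (29, 18 and 20 animals), and 98.6%, 87.4% and 90.8% of the 2368 genes kept their direction.

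Fatty acid oxidation genes rose in 17 of 18 muscle genes of the list, with the same count adjusted over the list alone (median 0.38, camera adjusted p = 8.51e-31, adjusted p = 0.0111 with an estimated correlation), among them Decr1 (0.58 ± 0.04), Hadhb (0.54 ± 0.05), Hadha (0.47 ± 0.05) and Acadvl (0.42 ± 0.04). PPAR targets rose in 9 of 18 (9 adjusted over the list alone; median 0.26, camera adjusted p = 6.28e-06, adjusted p = 0.295 with an estimated correlation), and lipid droplet genes rose in 5 and fell in 2 of 12 (6 and 2 adjusted over the list alone; median 0.13, camera adjusted p = 0.00864, adjusted p = 0.295 with an estimated correlation), with Cidea at 0.73 ± 0.11 and Pnpla2 at 0.36 ± 0.06. Glucose uptake and glycolysis genes fell in 7 and rose in 1 of 15 (10 and 2 adjusted over the list alone; median -0.15, camera adjusted p = 0.000211, adjusted p = 0.295 with an estimated correlation). Members were Slc2a4, the insulin-regulated glucose transporter (-0.19 ± 0.02), Gapdh (-0.26 ± 0.04), Aldoa (-0.26 ± 0.06) and Pygm (-0.25 ± 0.06). Fast fibre genes fell in 8 of 13 (10 adjusted over the list alone; median -0.24, camera adjusted p = 0.000208, adjusted p = 0.295 with an estimated correlation), such as Mylpf (-0.29 ± 0.08) and Casq1 (-0.24 ± 0.07), and without 1RC210 in 7 (median -0.18), with glycolysis genes then at a median of -0.09. None of 11 slow fibre genes passed in limma (median 0.13, -0.04 without 1RC210).

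Markers of other cell types moved with diet in muscle. Endothelial genes rose in 8 of 11 (10 adjusted over the list alone; median 0.16, camera adjusted p = 6.28e-06, adjusted p = 0.24 with an estimated correlation), such as Cldn5 (0.63 ± 0.11) and Kdr (0.34 ± 0.08). B cell genes rose in 7 of 11 (10 adjusted over the list alone; median 1.01, camera adjusted p = 0.000208, adjusted p = 0.387 with an estimated correlation), including Cd79b (1.10 ± 0.32), and adipocyte genes rose in 6 and fell in 1 of 17 (10 and 1 adjusted over the list alone; median 0.36, camera adjusted p = 0.00163, adjusted p = 0.387 with an estimated correlation), including Fabp4 (0.35 ± 0.08) and Lipe (0.36 ± 0.09). Erythroid genes fell in 4 of 5 (5 adjusted over the list alone; median -0.39, camera adjusted p = 0.000483, adjusted p = 0.295 with an estimated correlation), with Hbb-bt at -0.41 ± 0.09 and Hba-a1 at -0.39 ± 0.09. Unfolded protein response genes rose in 6 and fell in 1 of 17 (8 and 1 adjusted over the list alone; median 0.09, camera adjusted p = 0.000883, adjusted p = 0.295 with an estimated correlation), among them the chaperones Hspa5 (0.31 ± 0.05) and Hsp90b1 (0.21 ± 0.04).

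In C57BL/6J muscle Fabp3 rose 3.04-fold (log2 fold change 1.60 ± 0.17 (SE), n = 12 each, adjusted p = 6.12e-10), Acot2 2.9-fold and Slc25a34 2.84-fold. The fatty acid synthase Fasn fell 2.51-fold, Pfkfb3, a kinase of the glycolytic regulator fructose 2,6-bisphosphate, 1.88-fold and the sodium calcium exchanger Slc8a3 had -0.73 ± 0.18. Without 1RC210 the log2 fold change of Fabp3 was 1.37 and that of Pfkfb3 went from -0.91 to -0.58. Fatty acid oxidation genes rose in 15 of 18 (17 adjusted over the list alone; median 0.66, camera adjusted p = 1.48e-49, adjusted p = 0.000357 with an estimated correlation), and nuclear-encoded respiratory chain genes rose in 18 of 26 (24 adjusted over the list alone; median 0.19, camera adjusted p = 3.43e-23, adjusted p = 0.073 with an estimated correlation), among them Cycs (0.46 ± 0.06). Without 1RC210 these lists had 15 (median 0.57) and 17 genes higher (median 0.19). In DBA/2J the insulin receptor substrate Irs2 (ENSMUSG00000038894, chromosome 8, 10984681 to 11008458) rose 4.33-fold from 5.09 ± 0.52 to 7.2 ± 0.81 (SD, n = 12 each; adjusted p = 4.95e-06; log2 fold changes 1.40, 3.51 and 1.44 on days 5, 13 and 33), the phosphate transporter Slc20a1 3.35-fold and the transcription factor Klf4 3.13-fold. Dbp, a clock output gene, fell 2.72-fold, the alcohol dehydrogenase Adh1 2.55-fold and Cyp2e1 2.79-fold (adjusted p = 0.0414; leaving out any of 13 animals ended this call, up to 0.112 without 2RC200). Clock genes fell in 9 and rose in 3 of 18 (11 and 5 adjusted over the list alone; median -0.42, camera adjusted p = 0.0121, adjusted p = 0.244 with an estimated correlation), with Arntl at 1.61 ± 0.26, Clock at 0.63 ± 0.09 and Hlf at -0.84 ± 0.14. All 5 erythroid genes fell in DBA/2J (5 adjusted over the list alone; median -0.74, camera adjusted p = 2.54e-06, adjusted p = 0.21 with an estimated correlation).

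In BALB/cJ muscle the stress-inducible genes Ddit4 (5.88 ± 0.94 on RC, 4.27 ± 1.12 on HFD, SD, n = 12 each), Gadd45g and Depp1 fell 3.03-fold, 2.96-fold and 2.55-fold (adjusted p = 4.02e-05, 6.37e-06 and 6.37e-06). The apelin receptor Aplnr rose 2.16-fold, the ribosomal protein gene Rpl26, which has pseudogene copies, 1.75-fold and Rrad 1.88-fold (adjusted p = 0.0283; 0.0593 without 3HF201, 0.053 without 3HF228 and 0.0607 without 3RC252). B cell genes rose in 4 of 11 (10 adjusted over the list alone; median 1.83, camera adjusted p = 3.7e-05, adjusted p = 0.594 with an estimated correlation). These genes lie at low levels, as their mean had a median of -1.51 over the 72 muscle libraries and was highest in 3HF259 (3.76, the next library 2.36). Leaving out any animal kept the camera call (at most 0.000801).

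Over the 3 days 784 muscle genes passed in C57BL/6J, 1191 in DBA/2J and 1570 in BALB/cJ (1010 without 3RC209). With only genes of at least median level tested, DBA/2J had 746 and BALB/cJ 1038. The diet effect differed between strains for 1341 genes, including Klf4 (adjusted p = 2.13e-05), Depp1 (0.000122), Irs2 (0.000149), Ddit4 (0.00024) and Fabp3 (0.00416). Klf6, the gene of smallest p, had log2 fold changes of 0.02, 0.50 and -0.54 in C57BL/6J, DBA/2J and BALB/cJ (SE 0.09, adjusted p = 6.56e-07) and Klf2 0.09, 1.27 and -0.57 (SE 0.17). Slc20a1 had -0.31, 1.74 and 0.49 (SE 0.19), the small GTPase Rhob 0.32, 0.34 and -0.62 (SE 0.10), Gramd4 -0.17, 0.61 and 0.27 (SE 0.07) and Pcf11 -0.16, 0.63 and 0.00 (SE 0.08). BALB/cJ differed from DBA/2J in all 6 (adjusted p from 9.41e-08 to 0.0331) and DBA/2J from C57BL/6J in all but Rhob (0.957). Between C57BL/6J and BALB/cJ the effect differed for Klf6, Gramd4 and Rhob, and not for Slc20a1 (0.0534), Klf2 (0.0938) or Pcf11 (0.427). Respiratory chain genes responded lower in BALB/cJ than in C57BL/6J in 20 of 26 (25 adjusted over the list alone; median -0.30, camera adjusted p = 5.35e-22, adjusted p = 0.154 with an estimated correlation). Fatty acid oxidation genes did so in 13 of 18 (15 adjusted over the list alone; median -0.45, camera adjusted p = 2.55e-15, adjusted p = 0.154 with an estimated correlation). Without 1RC210 these numbers were 21 (median -0.28) and 13 (median -0.36).

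**Figure D3:**
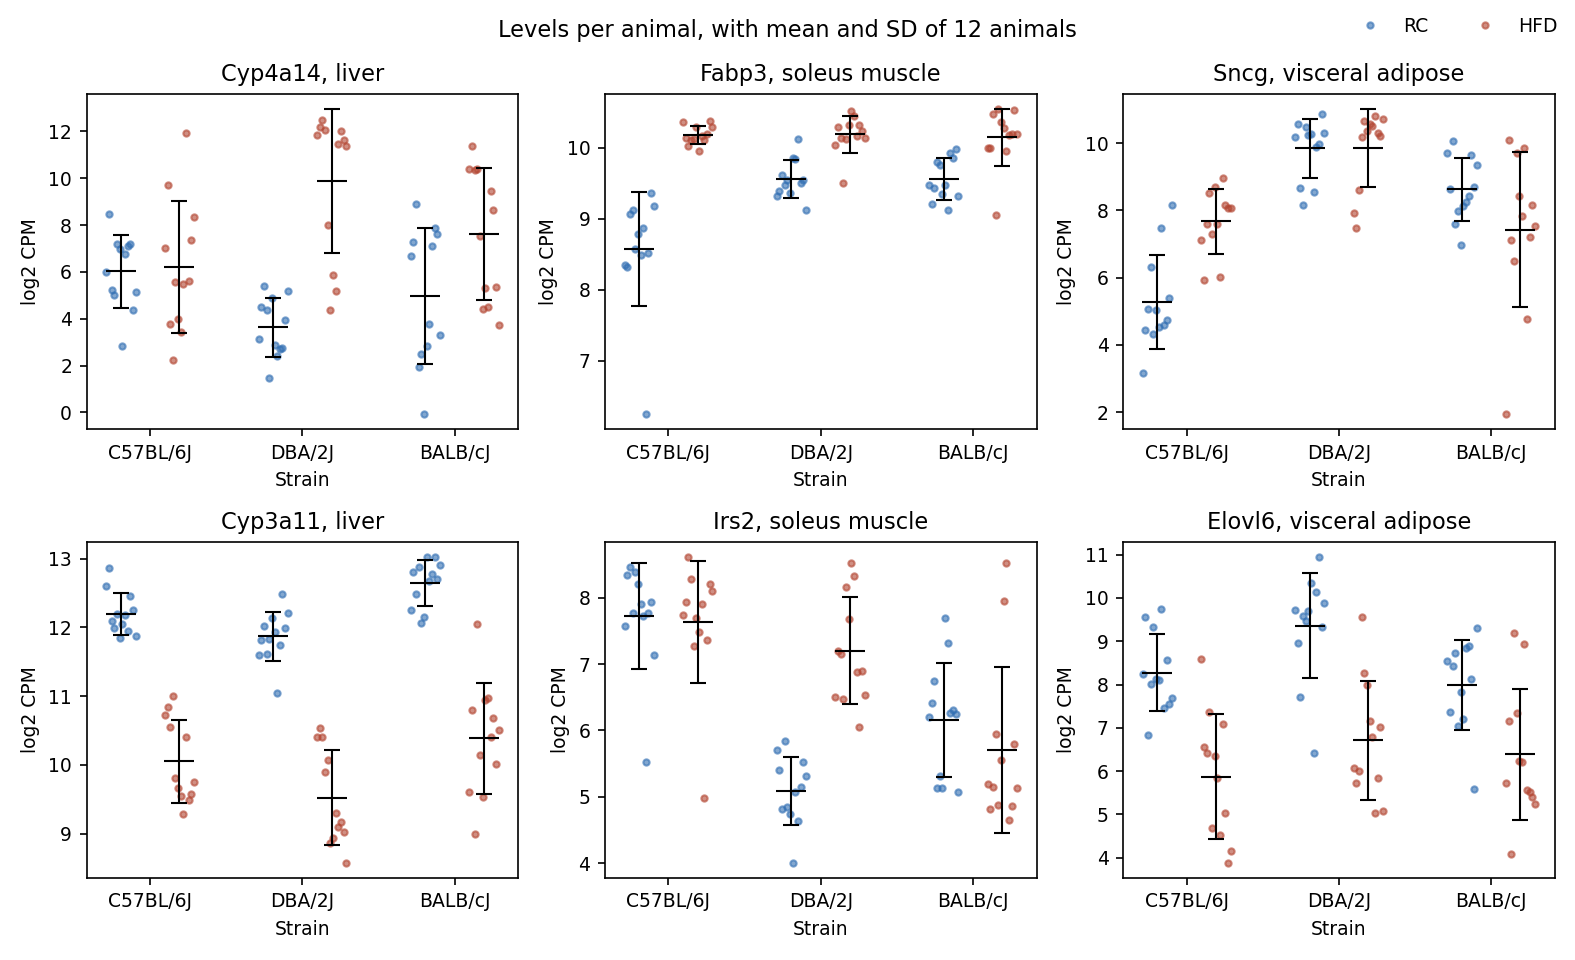
Levels (log2 CPM) of Cyp4a14 and Cyp3a11 in liver, Fabp3 and Irs2 in muscle, and Sncg and Elovl6 in adipose tissue, 1 point per animal by strain and diet, with the mean and SD of 12 animals. In DBA/2J Cyp4a14 had a mean of 9.88 on HFD and 3.64 on RC, and Irs2 7.2 and 5.09.

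Between days the diet effect in muscle differed for 135 genes, a count that leaving out any of 12 animals moved, from 71 without 3RC209 to 438 without 2RC203. The basement membrane collagens Col4a1 (-0.27, 0.54 and 0.63 on days 5, 13 and 33, adjusted p = 0.00114) and Col4a2 (-0.24, 0.44 and 0.58) were named with Depp1 (-0.15, 0.29 and -1.37) and the clock gene Per1 (-0.28, 0.38 and -1.0). By day 115, 78 and 590 genes passed in C57BL/6J, 6, 621 and 435 in DBA/2J, and 505, 8 and 517 in BALB/cJ. Without 1RC210 C57BL/6J had 134 on day 13 and 213 on day 5, DBA/2J 64 on day 5, and BALB/cJ 20 on day 13 and 827 on day 33. The 6 genes of DBA/2J on day 5, named after their values were seen, were the haemoglobin genes Hbb-bt (-1.65 ± 0.28) and Hbb-bs (-1.29 ± 0.27), the erythroid haem synthesis gene Alas2 (-1.45 ± 0.27), Kcng4 (-1.48 ± 0.29), Prdm2 (0.64 ± 0.11) and Gm26532 (1.29 ± 0.24). That count became 2 without 2RC200, 72 without 2RC203, 80 without 2HF200, 127 without 2HF202 and 292 without 2HF203. On day 33 in BALB/cJ 6 animals moved the count, from 80 without 3RC209 to 1430 without 3RC259, and on day 5 another 6, from 147 without 3HF201 to 952 without 3HF224. For DBA/2J the count was 349 on day 13 without 2RC231 and between 177 (without 2HF208) and 2.6e+02 (without 2HF210) on day 33 for 5 animals. With only the 8 animals compared in the fit limma called 0 genes in C57BL/6J on day 33 (1128 at an unadjusted p under 0.05), DBA/2J on day 5 (665) and BALB/cJ on day 13 (917), and 1 in BALB/cJ on day 5; voom was not run there. On day 33 C57BL/6J had 56 genes without 1RC210, 194 without 1HF259, 2.1e+02 without 1HF258, 1448 without 1RC235 and 1555 without 1RC256. On the other days its count ran from 36 (without 1HF250) to 71 (without 1RC248) on day 5 for 6 animals and from 19 (without 1RC228) to 47 (without 1RC229) on day 13 for 4. The 8 genes of BALB/cJ on day 13 became 7 with animals of 1 number as a block and 2 to 5 when 1 of 6 animals was left out (2 without 3RC255).

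On RC 5044 muscle genes differed between DBA/2J and C57BL/6J, 6071 between BALB/cJ and C57BL/6J and 5513 between BALB/cJ and DBA/2J. Myh6, the alpha cardiac myosin heavy chain, was 122-fold higher in DBA/2J and 77.8-fold higher in BALB/cJ than in C57BL/6J (log2 fold changes 6.93 ± 0.12 and 6.28 ± 0.12). Chmp4c (3.83 ± 0.16) was higher and Tmc7 (-3.06 ± 0.08) and Irs2 (-2.64 ± 0.31) were lower in DBA/2J than in C57BL/6J. The interferon-induced GTPase gene Gbp10 was higher in BALB/cJ than in C57BL/6J (4.39 ± 0.17) and DBA/2J (3.45). Tmc7 was also higher in BALB/cJ than in DBA/2J (3.18), while Rpl26 (-4.98 ± 0.10 and -5.17) and Rpl35a (-3.16 ± 0.08 and -3.21) were lower in BALB/cJ than in both others. Among check genes Alad (2.53 ± 0.11) and Glo1 (0.86) were higher in DBA/2J and Gpnmb (-0.51 ± 0.18, adjusted p = 0.0165) lower than in C57BL/6J. Nnt was higher in BALB/cJ (1.12 ± 0.19) and did not pass in DBA/2J (0.36, adjusted p = 0.13). Rpl26 and Rpl35a have pseudogene copies and Gbp10 has paralogs, so reads may be assigned to the wrong copy.

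Visceral adipose tissue showed lower expression of fatty acid synthesis on HFD. Elovl6 (ENSMUSG00000041220, chromosome 3, 129532355 to 129638495), an elongase of long-chain fatty acids, stood at 6.32 ± 1.44 on HFD and 8.54 ± 1.19 on RC (SD, n = 36 each), 4.64-fold lower (log2 fold change -2.22 ± 0.27 (SE), adjusted p = 2.63e-07). Fasn fell 4.28-fold, the acetyl-CoA carboxylase Acaca 3.64-fold, the ATP citrate lyase Acly 2.84-fold, the transketolase Tkt 2.71-fold, the malic enzyme Me1 2.7-fold and the parathyroid hormone receptor Pth1r 2.51-fold (adjusted p from 5.08e-05 to 0.00157). The imprinted gene Peg3 rose 2.33-fold (log2 fold change 1.22 ± 0.28, adjusted p = 0.00845), the collagen hydroxylase P4ha1 1.33-fold, and Rpl22l1 (0.65 ± 0.17), Ccdc117 (0.43 ± 0.08), Eif1 (0.39 ± 0.09), Stard3nl (0.37 ± 0.08) and Edrf1 (0.31 ± 0.06) were higher too. Atp5e was higher by 0.45 ± 0.12 (adjusted p = 0.0312), a call ended by leaving out 1RC254 (0.051), 2RC203 (0.0513), 2RC211 (0.051), 3RC255 (0.0516) or 3RC259 (0.0519). In 2 HFD libraries labelled BALB/cJ, 3HF201 (day 5) and 3HF208 (day 33), 14 of 14 measured pancreatic islet genes stood above all other 70 libraries, and adipocyte genes lay at medians of -8.23 and -5.98 (log2) from the rest of their groups. Without both libraries all of these genes still passed.

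**Figure D4:**
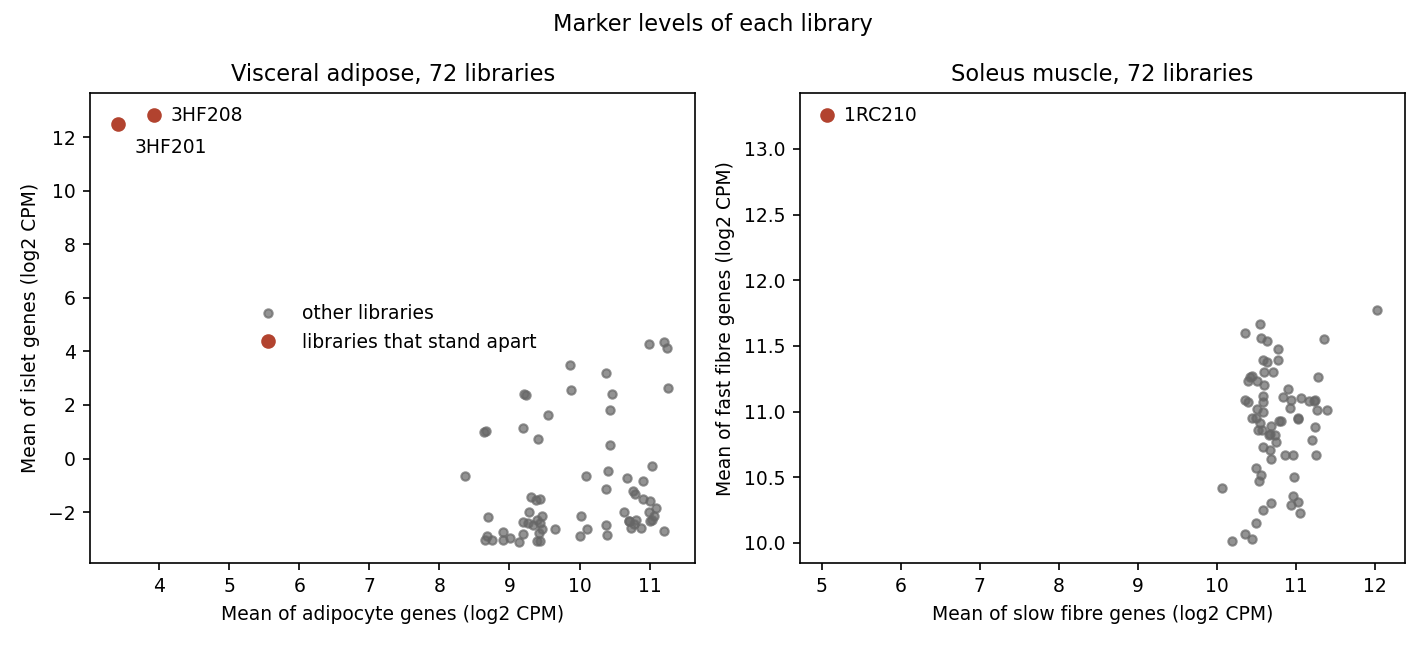
Mean level (log2 CPM) of islet against adipocyte genes in 72 adipose libraries and of fast against slow fibre genes in 72 soleus libraries, 1 point per library. In 3HF201 and 3HF208 the islet mean was 12.49 and 12.84, and in 1RC210 the slow fibre mean was 5.07.

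Of 16541 adipose genes 441 passed, 270 higher and 171 lower. Without the doubted pair of libraries 594 passed (342 of them higher), 383 of them shared. Within the lower number range 1369 genes passed, within the upper range 1, the fructose transporter Slc2a5 (-2.95 ± 0.33, adjusted p = 0.0171, named after its value was seen), and within the middle range limma called 0 (4381 at an unadjusted p under 0.05; voom was not run there). Of the 441 genes 99.1%, 91.4% and 96.4% kept their direction in the lower, middle and upper range, and with the range as a covariate 926 passed. Of 22 genes of fatty acid and triglyceride synthesis 10 fell (15 adjusted over the list alone; median -0.84, camera adjusted p = 7.62e-23, adjusted p = 0.134 with an estimated correlation), including Acss2 (-1.37 ± 0.24). Without both libraries 10 fell too (median -0.66). Cholesterol genes fell in 2 of 24, Nsdhl (-0.65 ± 0.16) and Pmvk (-0.54 ± 0.15; 8 adjusted over the list alone, median -0.17, camera adjusted p = 0.0014, adjusted p = 0.652 with an estimated correlation). Mitochondrially encoded respiratory genes fell in 1 of 7, mt-Nd5 (-0.73 ± 0.18; 6 adjusted over the list alone, median -0.47, camera adjusted p = 1.34e-05, adjusted p = 0.583 with an estimated correlation). Adipocyte and macrophage genes had medians of -0.35 and -0.15 with 0 of 17 and 0 of 21 passing, and camera called both (adjusted p = 0.0101 and 0.0121, and adjusted p = 0.789 and 0.652 with an estimated correlation). Without 3HF201 camera gave 0.157 and 0.0695 for these lists, without 3HF208 0.0959 and 0.0947, and without both 0.924 and 0.41. Muscle fibre genes in adipose tissue had medians of 1.05 (13 fast) and 0.69 (11 slow), with 0 members passing (camera adjusted p = 0.00193 and 0.0101, adjusted p = 0.652 with an estimated correlation for both). The fry test, which asks only whether a list moves on balance in 1 direction, gave an adjusted p = 0.00221 for the fatty acid synthesis list.

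Adipose libraries differed in lymphocyte transcripts. The mean of 11 B cell markers was above 5 in 40 libraries and below 5 in 32, with no value between 3.72 and 6.29, and 13583 of the 16541 genes followed it within groups (5977 rising, 7606 falling). It was above 5 on RC in 10 libraries of C57BL/6J, 3 of DBA/2J and 8 of BALB/cJ, and on HFD in 8, 4 and 7 (12 each). With this level as a covariate, a setting chosen after the values were seen, 2098 genes passed for diet (1228 higher, 870 lower), with all 441 among them. Without the doubted libraries as well 2964 passed.

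In C57BL/6J adipose tissue genes of adipose expansion were higher on HFD, and so were medians of muscle fibre genes. Mest (ENSMUSG00000051855, chromosome 6, 30723547 to 30748465), an imprinted gene that marks fat mass gain, rose 5.28-fold from 4.32 ± 1.1 to 6.72 ± 1.34 (SD, n = 12 each; log2 fold change 2.40 ± 0.45 (SE), adjusted p = 0.00758), and Sncg, gamma-synuclein, 5.27-fold (adjusted p = 0.0239). Adipose expansion genes had a median of 1.38 with 2 of 10 rising (9 adjusted over the list alone; camera adjusted p = 1.23e-11, adjusted p = 0.0227 with an estimated correlation), and a median of 1.02 with the B cell level. Medians of other lists, none with a member passing, were -1.37 for B cell, -0.72 for T cell, -0.57 for MHC class II, 0.53 for adipocyte, 1.58 for slow fibre, 1.40 for fast fibre and -1.86 for hepatocyte genes, so the make-up of these libraries may contribute. Emp1 rose 3.35-fold (adjusted p = 0.0457) and Elovl6 fell 5.25-fold (adjusted p = 0.0102). Single animals ended the calls of Sncg (9 animals, up to 0.0923 without 1RC226) and Emp1 (17 animals, up to 0.209 without 1HF231). In DBA/2J the Notch regulator Dtx4 rose 2.34-fold and the clock-controlled gene Noct (nocturnin) 1.95-fold (log2 fold change 0.96 ± 0.13, adjusted p = 6.75e-06). Elovl6 fell 6.25-fold (adjusted p = 0.00106), Dbp 4.06-fold (adjusted p = 0.00243) and Fasn 5.13-fold (adjusted p = 0.0348; 17 animals ended this call, up to 0.0869 without 2HF201). Clock genes fell in 6 and rose in 2 of 18 (11 and 4 adjusted over the list alone; median -0.76, camera adjusted p = 1.08e-09, adjusted p = 0.0589 with an estimated correlation), with Arntl at 2.01 ± 0.33, Ciart at -1.92 ± 0.31 and Bhlhe41 at -1.80 ± 0.31. In BALB/cJ Igip (0.69 ± 0.14), Dpysl2 (0.56 ± 0.13), Fpgt (0.49 ± 0.12), Sik1 (-0.94 ± 0.22) and Gm2a (-0.55 ± 0.13) passed with adjusted p values from 0.016 to 0.0378, and without 3HF201 and 3HF208 none did (0.133 to 0.295). With the B cell level in that fit Igip, Fpgt, Sik1 and Gm2a passed (0.0257 to 0.0382) and Dpysl2 did not (0.0511). Igip also lost its call without 3HF201 (0.0707), 3HF208 (0.0618) or 3HF230 (0.0554), and the other 4 when any of 8 to 14 animals was left out, up to 0.162 for Dpysl2.

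Within strains 19 adipose genes passed in C57BL/6J (16 higher, 3 lower), 68 in DBA/2J (26 higher, 42 lower) and 72 in BALB/cJ (37 higher, 35 lower). Without the doubted libraries these became 39, 166 and 0, the last by limma and by voom alike (1416 and 1345 genes at an unadjusted p under 0.05). With the B cell level as a covariate they were 53, 391 and 1839, and 205, 1134 and 159 without the doubted libraries as well. Quantile normalization gave 36 genes in C57BL/6J (26 higher, 10 lower) and 11 higher and 40 lower in DBA/2J. Leaving out 1 of 13 animals gave 7 (without 1HF231) to 38 genes (without 1RC256) in C57BL/6J, and 1 of 22 animals gave 1 (without 3HF201, 3HF208 or 3HF230) to 1113 genes (without 3HF202) in BALB/cJ. DBA/2J had 42 without 2RC211 or 2RC230, 43 without 2RC208 and 142 without 2HF203. The diet effect differed between strains for 14 genes (16 without the doubted libraries; 12 animals moved the count, from 9 without 1HF250 to 31 without 3RC251). Of the 6 genes of smallest p, Cebpd, Tsc22d3 and Errfi1 are known to respond to glucocorticoids. Cebpd had log2 fold changes of 0.54, 0.16 and -1.17 in C57BL/6J, DBA/2J and BALB/cJ (SE 0.20, adjusted p = 0.00601), Tsc22d3 0.50, 0.35 and -1.08 (SE 0.22) and Errfi1 0.59, 0.61 and -1.07 (SE 0.24). Noct had 0.48, 0.96 and -0.04 (SE 0.13), the clock repressor Bhlhe41 -0.13, -1.80 and 0.55 (SE 0.31) and the taurine transporter Slc6a6 -0.06, -0.80 and 0.31 (SE 0.14). BALB/cJ differed from C57BL/6J for Cebpd (adjusted p = 0.00303), Tsc22d3 (0.0117) and Errfi1 (0.0198), and from DBA/2J for Slc6a6 (0.00571), Noct (0.00571), Bhlhe41 (0.00901) and Errfi1 (0.0242). No pairwise difference between DBA/2J and C57BL/6J passed for these 6 (0.409 to 0.989). Without the doubted libraries all 6 passed the test between strains (0.00775 to 0.0177).

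By day 1769 genes passed in BALB/cJ adipose tissue on day 33 (517 higher, 1252 lower), and 299 without the doubted libraries (69 higher, 230 lower; 207 shared). The count was 40 without 3RC209, 43 without 3HF208, 212 without 3RC259, 491 without 3RC208 and 3140 without 3RC211. DBA/2J had 41 genes on day 33 (140 without the doubted libraries; 20 without 2HF209, 21 without 2RC208, 23 without 2RC211, 25 without 2RC209 and 70 without 2HF210). It had 354 with the B cell level as a covariate, and 1332 without the doubted libraries as well, and BALB/cJ on day 33 had 2200 and 108. The other days gave 1 gene or 0. Named after their values were seen, these were the myosin gene Myh7b in C57BL/6J on day 33 (4.20 ± 0.78, adjusted p = 0.0255), Dyrk2 in DBA/2J on day 5 (0.55 ± 0.11, adjusted p = 0.0477) and Slc6a6 in DBA/2J on day 13 (-1.46 ± 0.24, adjusted p = 0.00159). The count of C57BL/6J became 0 without 1HF257, 1HF258, 1HF259, 1RC210, 1RC211 or 1RC235, 2 without 1RC256 and 5 without 1HF209. That of DBA/2J became 0 on day 5 without 2HF201, 2HF202, 2RC200, 2RC201 or 2RC203 and 9 without 2HF203, and on day 13 it became 0 without 2HF255 and 2 without 2HF230. Voom called 0 genes in C57BL/6J on day 33 (332 at an unadjusted p under 0.05) and in DBA/2J on day 5 (741). With only the 8 animals compared in the fit limma called 0 in BALB/cJ on day 33 (3278 at an unadjusted p under 0.05). Limma called 0 genes in C57BL/6J on day 5 (718 at an unadjusted p under 0.05) and day 13 (163), and in BALB/cJ on day 5 (1827) and day 13 (1036), and voom called 0 in each. The B cell level gave C57BL/6J 4 genes on day 13 and 3 on day 33, DBA/2J 3 on day 13 and BALB/cJ 29 on day 5; without the doubted libraries as well these were 20, 67, 41 and 8. In BALB/cJ on day 5 leaving out 3HF224, 3HF203, 3RC251 or 3HF202 gave 19, 20, 27 and 302 genes. The effect differed between days for 0 genes by limma (892 at an unadjusted p under 0.05) and by voom (741).

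On RC 6902 adipose genes differed between DBA/2J and C57BL/6J, 1859 between BALB/cJ and C57BL/6J and 2687 between BALB/cJ and DBA/2J (4097 without the doubted libraries, 4610 without 2RC231). With the number range as a covariate the first of these counts was 3827. The B cell level as a covariate gave 2322, 2945 and 2831, so part of the difference between DBA/2J and C57BL/6J may go with that level. Sncg was 23.8-fold higher in DBA/2J and 10.2-fold higher in BALB/cJ than in C57BL/6J (13.6-fold and 8.02-fold with the B cell level), and Mest 53.8-fold lower in BALB/cJ than in DBA/2J (log2 fold change -5.75 ± 0.45, adjusted p = 8.99e-16; 34.1-fold with the B cell level). The scavenger receptor gene Marco (-5.42 ± 1.26, and -1.48 ± 0.31 with the B cell level) and Mndal (-5.77 ± 0.59) were lower in DBA/2J than in C57BL/6J, Tpm3-rs7 higher in DBA/2J and BALB/cJ (4.62 ± 0.39 and 4.85), and H2-Q7 (-4.61 ± 0.59) and Rpl26 (-4.55 ± 0.38) lower in BALB/cJ than in C57BL/6J. Mndal (4.81) and Gbp2b (2.93 ± 0.74) were higher and Rpl26 (-4.01) lower in BALB/cJ than in DBA/2J. Klrd1, a natural killer cell receptor gene that DBA/2J mice lack, was lower in DBA/2J than in C57BL/6J (-2.71 ± 0.74, adjusted p = 0.00421), and did not pass with the B cell level (-0.48, adjusted p = 0.293). Mndal, H2-Q7, Tpm3-rs7, Gbp2b and Rpl26 have close copies, so their values are uncertain.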

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

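The mixing tests, the test of another tissue alone and the fits without doubted libraries were chosen only after the result was seen; the other tests here were not. Each of the 54 groups of 4 animals was looked at for read depth and, in muscle and adipose tissue, for 2 marker list means, 126 looks in all. In 16 of these, in 13 groups, 1 animal lay far from the other 3, and chance alone gives that in about 1 in 20 looks.

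In the adipose libraries labelled 3HF201 and 3HF208 the mean of 14 measured islet genes was 12.49 and 12.84 against 2.42 to 2.63 and 0.99 to 2.39 in the rest of their groups, with Ins2 at 17.81 and 18.39 (at most 8.19 elsewhere), and the adipocyte mean of 3HF208 was 3.93 against 8.63 to 9.24. Islet RNA as a minor part of an adipose library would lower adipocyte genes by less than 1 (log2), and the smaller of the medians was -5.98, which argues against it. Of 128 strain genes only 33.6% of those of 3HF208 matched BALB/cJ while 91.4% matched C57BL/6J, and 3HF201 matched DBA/2J for 89.1% and BALB/cJ for 50.8%, whereas liver and muscle of both animals matched BALB/cJ for at least 95.1%. Another tissue alone, which should spoil the match to any strain, is argued against by the lower best match of 89.1%. The 50.8% of 3HF201 lies within the 46.9% to 51.6% of libraries labelled DBA/2J, while the other libraries labelled BALB/cJ matched that strain for at least 93%. Libraries of other animals and of tissue rich in islets may have been recorded under these labels, which stays a hypothesis with no source found, and no biological explanation was tested.

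In the muscle library 1RC210 the mean of slow fibre genes was 5.07 against 10.64 to 10.75 in the other 3 chow animals of C57BL/6J on day 33, with Myh7 at 6.2 (at least 12.11 elsewhere) and Myh4 at 15.62 (at most 11.83 elsewhere). Fast muscle as a minor part of a soleus library would lower slow fibre genes by less than 1 (log2), and their median lay at -6.29, which argues against it. A library from another strain is argued against by a match to C57BL/6J for 93.4% of 122 strain genes. Another leg muscle taken in place of soleus may account for the values and was not tested, and no biological explanation was tested.

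Medians of listed stress and fasting genes lay below 0 with HFD in BALB/cJ on days 5 and 33 in all 3 tissues, none of them past the threshold, and above 0 on day 13 (0.42 in liver, 0.05 in muscle and 0.76 in adipose tissue). If a weaker glucocorticoid and fasting response at sampling were the cause, listed genes not looked at before should have medians below -0.3 in all 3 tissues on both days, and the highest of the 6 medians was -0.16 (muscle, day 5), with none above 0. On day 33 the medians were -1.82 in liver (12 of 13 genes lower), -1.23 in muscle (13 of 14) and -1.97 in adipose tissue (12 of 14, 3HF208 included), with an adjusted p = 0.42 in each (exact permutation, 4 animals against 4). In adipose tissue the day 5 median of -0.93 includes 3HF201, and without both libraries the medians were -0.52 on day 5 (14 of 14 lower) and -1.99 on day 33 (11 of 14). For a shift of clock phase, output genes minus genes of opposite phase differed in liver by 1.14 on day 5 and by -0.08 on day 33, the smaller value being short of the shift required on both days. Neither could be excluded, and a difference in handling or feeding before sampling, or a strain's own response to diet, may also be the cause and cannot be told apart with these values.

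Other groups with 1 animal apart were as follows. Adipocyte means in adipose tissue were 10.71 in 1RC254 (others 9.19 to 9.4), 9.01 in 1RC226 (9.39 to 9.43) and 8.91 in 2RC231 (10.76 to 10.91). The islet mean was 0.74 in 1RC251 (others -3.07 to -2.42). Depth was 37.05 M reads in adipose library 2RC200 (others 24.29 to 26.14), 18.08 in liver library 3HF254 (25.96 to 27.27) and 22.42 in muscle library 1RC226 (29.28 to 30.05). Slow fibre means in muscle were 10.56 in 3RC252 (others 10.67 to 10.69), 10.9 in 1HF225 (10.58 to 10.6), 10.4 in 1RC226 (10.77 to 10.78) and 11.03 in 2RC230 (11.24 to 11.28). The fast fibre mean was 11.77 in 2HF201 (others 11.01 to 11.08).

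The effect of diet differed between strains by the interaction test for 1974 liver genes, with adjusted p = 1.16e-10 for Slc46a3, 5.3e-08 for Hsdl2, 5.56e-08 for C2, 1.77e-07 for Gpr155 and for Irf7, and 2.64e-07 for Prnp. It differed for 1341 muscle genes, with 6.56e-07 for Klf6, 1.12e-06 for Gramd4, 2.09e-06 for Rhob, 2.12e-06 for Slc20a1, 4.91e-06 for Klf2 and 1.07e-05 for Pcf11. For adipose tissue the count was 14, with 0.00601 for Cebpd, 0.00988 for Slc6a6, Errfi1 and Tsc22d3, 0.011 for Noct and 0.0126 for Bhlhe41. Between days it differed for 422 liver genes, with 4.51e-05 for Ginm1 and Ces3a and 8e-05 for Tnfaip8l1, and for 135 muscle genes, with 0.000987 for Depp1, 0.00114 for Col4a1, and 0.00274 for Col4a2 and Per1. Chance was excluded at 1 of 100 splits for both liver counts (highest other 547 between strains and 2.6e+02 between days) and both muscle counts (813 and 30), and at 3 of 100 for the 14 adipose genes. In adipose tissue another split gave 3690 genes, many times the real count, which points to a structure of the samples.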

How the results depend on the processing

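Voom, the fits within number ranges, those with the B cell level as a covariate and those without doubted libraries were added after seeing the data. The repeat-library alternative was not run, as the tables used held no such columns, and the pseudocount alternative has no place with log2 values. Testing without a filter is void, since the filter left out 0 genes in liver and muscle and 1 in adipose tissue. The median change of all genes, over all strains and days and within each strain, moved by less than 0.1 (log2) with each filter, quantile normalization, no variance trend, the number range, voom, the B cell level and without doubted libraries; it was not computed under the other settings. Of 205 gene values checked, 3 changed direction or side of the threshold with quantile normalization, 1 without the variance trend, 7 with the number range and 5 with voom. With the stricter filter 2 of 184 did, and without doubted libraries 8 of 137. With the B cell level 4 of 66 adipose values did, and 6 when doubted libraries were left out as well. Reversed were Gpnmb in adipose tissue (DBA/2J against C57BL/6J on RC, -0.27 to 0.404, number range) and Glo1 in liver (BALB/cJ against DBA/2J, 0.02 to -0.007 with the number range and -0.024 with quantile normalization). With the B cell level as a covariate BALB/cJ against DBA/2J on RC reversed in adipose tissue for Klrd1 (1.26 to -0.011) and for Glo1 (-0.08 to 0.124, and 0.144 without doubted libraries as well). None of these had passed. Camera called as many lists in many random splits, and with an estimated correlation the lists called for the effect over all strains and days fell to 2 in liver, 1 in muscle and 0 in adipose tissue. Depth was not lowered as an alternative; at 4 animals against 4, simulated log2 changes of 0.5 were recovered for 1.5% of genes in adipose tissue. Where an alternative removes genes or animals its own construction lowers or raises counts; otherwise the cause was not tested. Counts of called genes that moved by over 1.5 times follow (from 0, any change), and those written as 2.0e+02 are rounded to 2 digits.

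The stricter filter tests fewer genes. It gave in liver 1661 over all strains and days, 1718 in DBA/2J, 1016 in BALB/cJ, 9 in C57BL/6J on day 5, 123 and 1330 in DBA/2J on days 13 and 33, 868 and 739 in BALB/cJ on days 5 and 33, and 1192 for diet by strain. On RC it gave 2987 (DBA/2J against C57BL/6J), 2923 (BALB/cJ against C57BL/6J) and 2683 (BALB/cJ against DBA/2J). In muscle it gave 746 in DBA/2J, 1038 in BALB/cJ, 21 and 377 in DBA/2J on days 5 and 13, 265, 2 and 338 in BALB/cJ on days 5, 13 and 33, and on RC 2625, 3192 and 2752. In adipose tissue it gave 4 in C57BL/6J, 39 in BALB/cJ, 0 in C57BL/6J on day 33 (82 at an unadjusted p under 0.05), 2 in DBA/2J on day 13, and on RC 3489, 567 and 996.

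Quantile normalization gave 2.0e+02 in muscle of C57BL/6J on day 5, 16 of DBA/2J on day 5 and 1 of BALB/cJ on day 13, and in adipose tissue 36 in C57BL/6J, 65 in DBA/2J on day 33 and 0 on day 5 (674 unadjusted). No variance trend gave 15 in muscle of BALB/cJ on day 13 and 0 in adipose tissue of DBA/2J on day 5 (662 unadjusted). Voom gave 9 adipose genes for diet by strain. The number range as a covariate gave in muscle 392 in C57BL/6J on day 33, 36 in DBA/2J on day 5, 318 in BALB/cJ on day 33 and 80 for diet by day. In adipose tissue it gave 926 over all strains and days (618 higher, 308 lower), 961 in BALB/cJ, 3209 on its day 33, 0 in C57BL/6J on day 33 (495 unadjusted) and 3827 on RC (DBA/2J against C57BL/6J). Within the lower range 1346 muscle and 1369 adipose genes passed, within the middle range 119 in liver, 1063 in muscle and 0 in adipose tissue (4381 unadjusted), and within the upper range 221, 163 and 1.

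Only the animals compared gave in liver 1 and 10 in C57BL/6J on days 5 and 33, 951 in DBA/2J on day 13, and 38, 14 and 574 in BALB/cJ. In muscle it gave 45, 373 and 0 (1128 unadjusted) in C57BL/6J, 0 (665) and 802 in DBA/2J on days 5 and 33, and 1, 0 (917) and 205 in BALB/cJ. In adipose tissue it gave 0 in C57BL/6J on day 33 (635), 0 (292), 0 (410) and 157 in DBA/2J and 0 in BALB/cJ on day 33 (3278). Only the strain's animals gave 183 and 961 in liver of C57BL/6J and BALB/cJ, and 30 and 0 (1360 unadjusted) in adipose tissue. The animal number as a block gave in liver 1439 and 794 in DBA/2J on days 5 and 33, and 390 and 1 in BALB/cJ on days 5 and 13. In muscle it gave 0 (568 unadjusted) and 2.0e+02 in DBA/2J on days 5 and 33 and 1133 in BALB/cJ on day 5, and in adipose tissue 0 (66) and 0 (2064) in DBA/2J on days 5 and 33. Numbers pair the animals on day 13 in BALB/cJ liver and muscle, so the other block values are hints.

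Without doubted libraries muscle had 213, 134 and 56 genes in C57BL/6J on days 5, 13 and 33, 64 in DBA/2J on day 5, and 20 and 827 in BALB/cJ on days 13 and 33. Adipose tissue had 39 in C57BL/6J, 166 in DBA/2J, 0 in BALB/cJ (1416 unadjusted), 2 in C57BL/6J on day 33, 2 and 140 in DBA/2J on days 13 and 33, 299 in BALB/cJ on day 33, and 4097 on RC (BALB/cJ against DBA/2J).

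The B cell level as a covariate gave in adipose tissue 2098 genes over all strains and days, 53 in C57BL/6J, 391 in DBA/2J and 1839 in BALB/cJ. By day it gave 4 and 3 in C57BL/6J on days 13 and 33, 3 and 354 in DBA/2J on days 13 and 33 and 29 in BALB/cJ on day 5. It gave 49 for diet by strain, and on RC 2322 for DBA/2J and 2945 for BALB/cJ, each against C57BL/6J. Without doubted libraries as well it gave 2964 over all strains and days, and 205, 1134 and 159 within strains (same order). By day it then gave 20 and 67 in C57BL/6J on days 13 and 33, 41 and 1332 in DBA/2J on days 13 and 33, and 8 and 108 in BALB/cJ on days 5 and 33. Diet by strain had 67 genes, and RC 3483, 4434 and 4403 (BALB/cJ against DBA/2J last).

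Leaving out 1 animal gave ranges of 11 to 30, 22 to 62 and 24 to 2.2e+02 in liver of C57BL/6J on days 5, 13 and 33, 547 to 818 and 66 to 159 in DBA/2J on days 5 and 13, and 761 to 2501, 20 to 69 and 551 to 1662 in BALB/cJ. In muscle these were 36 to 130, 19 to 66 and 56 to 1555, then 2 to 292, 349 to 525 and 177 to 519, then 147 to 952, 2 to 10 and 80 to 1430. Muscle had 1010 to 2201 in BALB/cJ and 71 to 438 for diet by day. In adipose tissue the ranges were 7 to 38 in C57BL/6J, 42 to 142 in DBA/2J, 1 to 1113 in BALB/cJ and 9 to 31 for diet by strain. By day they were 0 to 5 in C57BL/6J on day 33, 0 to 9, 0 to 2 and 20 to 70 in DBA/2J, and 0 to 302 and 40 to 3140 in BALB/cJ on days 5 and 33. On RC the range was 1956 to 4610 for BALB/cJ against DBA/2J.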

Other observations

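The test of clock phase by strain and the look at B cell markers in this part were chosen only after the result was seen; the counts over other splits were not.

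Clock output genes (Dbp, Tef, Hlf, Nr1d1, Nr1d2 and Per3) were lower and genes of opposite phase (Arntl, Clock, Npas2 and Nfil3) higher with HFD in all 3 tissues of DBA/2J. The mean log2 fold change of output minus opposite genes was -2.1 in liver (adjusted p = 0.00042), -1.9 in muscle (0.000105) and -2.58 in adipose tissue (0.000131), by exact permutation of diet within days over 343000 reassignments (n = 12 each, 9 tests). In C57BL/6J and BALB/cJ the mean over days lay between -0.18 and 0.32 (adjusted p = 0.925 in each test), but days differed: C57BL/6J had 0.93, 1.25 and -2.45 in liver on days 5, 13 and 33, 1.07, 0.15 and -1.02 in muscle and 0.90, 0.17 and -0.87 in adipose tissue, and BALB/cJ had 1.14 in liver on day 5. None of these passed (adjusted p from 0.231 to 0.943, exact permutation, 4 animals against 4), so a shift on single days in these strains is left open. Whether strains differ in this measure was not tested here, and the time of day of sampling was not analysed here.

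In liver and muscle genes called in 1 strain were shared with the others beyond the number expected if calls were independent. In liver 329 genes were lower in BALB/cJ and DBA/2J (95.7 expected, Fisher's exact p = 3.52e-105) and 245 higher (105.1 expected, p = 2.06e-40). By Fisher's exact test BALB/cJ and C57BL/6J shared 77 lower genes (11.2 expected, p = 2.03e-46), and DBA/2J and C57BL/6J 56 (17.8 expected, p = 9.33e-16). In muscle BALB/cJ and DBA/2J shared 143 higher (45 expected) and 114 lower genes (24.8 expected). In adipose tissue each pair of strains shared 0 higher genes and 1 to 3 lower genes. Genes are not independent replicates, so these p values describe overlap only. Each strain had its own chow animals.

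Other splits of the same animals were counted for each result. Chance was excluded, with 1 of 100 splits as large, for liver overall (2676 genes, highest other 137), C57BL/6J (291 and 62) and DBA/2J (2718 and 176), and for muscle overall (2368 and 21), C57BL/6J (784 and 10) and DBA/2J (1191 and 44). The same held for adipose tissue of C57BL/6J (19 and 5). On RC it held in liver for DBA/2J against C57BL/6J (6071 and 3162), BALB/cJ against C57BL/6J (5899 and 2809) and BALB/cJ against DBA/2J (5310 and 944). In muscle it held in the same order (5044 and 2149, 6071 and 3287, 5513 and 923), and in adipose tissue for BALB/cJ against C57BL/6J (1859 and 437). Chance was also excluded, with 2 of 100 splits as large, for BALB/cJ in liver (1866 and 2069) and muscle (1570 and 1802), and for adipose tissue overall (441 and 3811), in DBA/2J (68 and 98) and on RC for DBA/2J against C57BL/6J (6902 and 9817) and against BALB/cJ (2687 and 3829). It was not excluded for adipose tissue of BALB/cJ (72 genes, 8 of 100 splits, highest other 4311), and the adipose count between days was 0 (892 at an unadjusted p under 0.05 by limma; 100 of 100 splits, highest other 4460). The number of lists called by camera overall was not beyond chance: 8 in liver (52 of 100 splits, highest other 15), 16 in muscle (7 of 100, 19) and 11 in adipose tissue (58 of 100, 19). Adipose splits that called many times the real count, with and without the libraries 3HF201 and 3HF208 among their animals, point to a structure of the samples.

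For 4 animals against 4, 35 splits were counted. Chance was excluded at 1 of 35 for liver of C57BL/6J on day 33 (115 genes, highest other 87), of DBA/2J on day 5 (879 and 2), day 13 (241 and 1) and day 33 (2005 and 510) and of BALB/cJ on day 33 (1210 and 875). The same held for muscle of C57BL/6J on day 5 (115 and 2) and day 13 (78 and 7) and of DBA/2J on day 13 (621 and 2) and day 33 (435 and 142), and for adipose tissue of DBA/2J on day 33, by 1 gene (41 and 40). For adipose tissue of C57BL/6J on day 33 the split count was also 1 of 35 (1 gene, highest other 0), but leaving out any of 6 animals or using voom brought it to 0, so chance is left open. With 2 of 35 splits as large, a share over 0.05, chance was not excluded for liver of C57BL/6J on day 5 (17 and 151) and day 13 (40 and 349) and of BALB/cJ on day 5 (1574 and 2385) and day 13 (46 and 1251). Nor was it for muscle of C57BL/6J on day 33 (590 and 767) and BALB/cJ on day 5 (505 and 746) and day 33 (517 and 522), or adipose tissue of BALB/cJ on day 33 (1769 and 6485). Further counts were 3 of 35 for muscle of BALB/cJ on day 13 (8 and 540) and adipose tissue of DBA/2J on day 13 (1 and 14), 4 of 35 for adipose tissue of DBA/2J on day 5 (1 and 5277) and 8 of 35 for muscle of DBA/2J on day 5 (6 and 1247). In adipose tissue 35 of 35 splits gave at least the 0 genes called by limma in C57BL/6J on day 5 (718 at an unadjusted p under 0.05) and day 13 (163) and in BALB/cJ on day 5 (1827; highest other 4451) and day 13 (1036).

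The highest other split parted the middle from the upper number range in liver of C57BL/6J and BALB/cJ and in muscle of BALB/cJ on day 13, and the lower from the upper range in muscle of BALB/cJ on day 33. With the number as a block the day 13 counts of BALB/cJ were 1 in liver and 7 in muscle. With the range as a covariate muscle of BALB/cJ on day 33 had 318 genes. On day 5 in BALB/cJ the highest other split of liver and of muscle exchanged 3HF224 and 3RC251, which had middle and upper numbers while the others had lower ones. In 3 adipose groups the highest other split parted libraries by the mean of B cell markers. Those above 5 were 4 of 4 on one side and 1 of 4 on the other in DBA/2J on day 5, 4 and 0 in BALB/cJ on day 5, and 4 and 1 in BALB/cJ on day 33. The source of these transcripts was not tested. The splits by number, which called up to many times the real count, point to a structure of the samples by animal number. Between number ranges 3048 genes differed in liver, 387 in muscle and 187 in adipose tissue.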
